A study of Homo sapiens with 6 samples.

How the data were processed

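Gene expression was measured by RNA sequencing in 6 libraries of MDA-MB-231, a human cell line derived from a triple-negative breast tumour. Per the labels, 3 libraries came from cells transfected with a control siRNA (siControl) and 3 from cells transfected with siRNA against PHF20L1 (siPHF20L1). An siRNA is a short double-stranded RNA that leads to cleavage of transcripts it pairs with in full. The labels' protocols name a pair of lipid transfection reagents without saying which one served which sample. Neither the siRNA sequences nor the time of harvest was given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

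Per the labels' protocols, poly-A RNA was selected, fragmented and made into libraries with a stranded mRNA kit. The submitters' processing notes name Bowtie 0.12.2, TopHat2 2.1.1 and HTSeq 0.6.0 with the genome build GRCh37, with no role or order for the tools. Per the file headers, the deposited unit is FPKM, fragments scaled to transcript length and to the number of mapped fragments of the library, with 1 value per gene and library. How the authors computed the FPKM, with which annotation, and whether the counting used strand were not given in the sources used here. Values of a gene and of a partner that overlaps it on the opposite strand are therefore uncertain, as are those of near-identical family members such as histone genes. Each file listed the same 17452 genes under Entrez gene identifiers, and FPKM were written to 2 decimals. For 26 genes a date stood in place of the symbol, and the symbol was taken from the reference table through the Entrez identifier. Of the 17452 identifiers, 17419 were found in the reference gene table. The reference annotation used here, GENCODE release 29, belongs to another build, so it served only for transcript sequences and lengths, and no coordinates are given.

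The FPKM of 1 library summed to between 395250.9 and 416138.4. Depth was estimated from the files themselves. In genes with transcripts shorter than 1500 nt and very low FPKM, the product of FPKM and length moved in steps of what 1 fragment is worth. These steps put the depth between 17200000 and 17500000 fragments per library, with 95% bootstrap limits (200 resamples) between 16900000 and 17600000 fragments. A single fragment in a transcript of 1 kb was thus worth 0.0573 to 0.0583 FPKM. The limits cover the estimate of the step only. The search covered a narrow range of steps, and a true step that is a whole multiple of the one found would score as well. A lower depth was therefore not excluded. None of 20 widely used housekeeping genes was at 0 in any library. The files held 788 genes listed at 0 in all 6 libraries.

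The replicates were compared before they were averaged. From the approximate fragment numbers, the libraries numbered 2 and 3 differed by a mean chi-square per gene of 2.25 in the siControl group and 2.00 in the siPHF20L1 group, over genes with at least 40 fragments, with medians of 0.73 and 0.68. Counting noise alone gives a mean of 1 and a lower median, so the medians are not to be set against 1. Pairs that included a library numbered 1 gave 11.46 to 14.62. The libraries numbered 2 and 3 were thus very close, and were kept as separate samples as labelled. Their mean lay above that of counting noise if the estimated depth holds. These values do not tell separate cultures from repeat libraries of 1 culture. The count of genes with these libraries averaged is given as an alternative. The replicate numbers were checked for pairing through the correlation, across genes, of the deviations from the group means. Same-numbered libraries gave 0.73, 0.44 and 0.42 for the numbers 1, 2 and 3, all above 0.1. Deviations within a group of 3 sum to 0. With the number 1 apart in both groups, values above 0 among the numbers 2 and 3 therefore follow without any pairing. siControl 3 with siPHF20L1 2 gave 0.49, above the same-numbered pairs of these libraries, so that this check sets the number 1 apart but does not separate the numbers 2 and 3. No fit had the number 1 as a batch of its own. The main fit had no block, so the shared deviation of these libraries stayed in its spread, and the block among the alternatives used all 3 numbers. Values within the number 1 (1 library against 1, no test) and within the numbers 2 and 3 are given beside the main ones.

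The test fixed before the data were examined was a count-based one, with limma for the case that the files held normalized values. Because the deposited values are FPKM, limma 3.58.1 (R 4.3.3) was used on log2(FPKM + 1), with an intensity trend in the prior variance and no block. A gene was tested if its FPKM was at least 1 in at least 3 libraries, which left 11560 genes. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, siPHF20L1 minus siControl, and understate the change of low genes. Fold values are ratios of mean FPKM. A rank or permutation test of 3 against 3 libraries cannot give an exact p under 0.1, so none was used for single genes. On simulated data with the real means and spread, in which 200 of the 11560 genes were changed, the limma step recovered 65% of genes changed by 0.5 and 95.2% of genes changed by 1 on the log2 scale. False calls made up 6.3% of all calls. The simulated libraries were independent of each other and few genes changed, unlike in the real data, so these rates may not carry over.

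Before the data were examined, 44 gene lists with 943 entries were fixed from textbook knowledge, covering chromatin complexes, metabolism, cell cycle, stress, immune, adhesion and lineage genes. They include markers of other cell types that a culture could hold. Of these lists, 43 had members among the genes tested, and the list of mitochondrial genome transcripts had none in the tables used here. The 41 lists with at least 5 tested members were tested with camera of limma (preset correlation of 0.01), adjusted over the 41 lists. Camera compares the members with all other genes. In simulated data, a shift of 0.3 in the glycolysis list was recovered in 20 of 20 runs, with 1 call in 780 tests of other lists. Such runs are no guide to false calls where members of a list vary together. The correlation estimated in the real data was 0.172 for glycolysis and 0.408 for ribosomal proteins, while that of the hypoxia list was -0.019. With an estimated correlation, camera also takes its degrees of freedom from the few libraries instead of the many genes. Few lists can pass in that setting, whatever their correlation. In 31 of the 43 lists the counts of members past the threshold were the same when adjusted over the list alone, and in the other 12 they differed by at most 2. The list of reported PHF20L1 targets (HIC1, KISS1 and BRCA1) holds genes named by the study on this cell line, possibly on these libraries.

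The genes named were fixed by rule. They are PHF20L1 and its paralog PHF20, the reported targets, and in each direction the 12 genes with the largest log2 difference that passed the threshold, had a mean FPKM of at least 2 and did not overlap between the groups. Pseudogenes, antisense genes and clone-named loci were left out. From each list, up to 4 members with the smallest p could be named. Some of these genes are not reported here.

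The alternatives planned were quantile normalization, a pseudocount of 0.1, no filter, a filter at an FPKM of 2, the replicate number as a block, leaving out each library, camera with an estimated correlation, and fry of limma. Those added after the data were seen were scaling to equal FPKM sums, median-ratio size factors, the libraries numbered 2 and 3 alone, these libraries averaged as 1 per group, and lists without genes that carry certain 3′ UTR words. In the last, every carrier was left out of the 11560 genes, not of the list alone. This left 5963 genes with a median log2 difference of 0.091, against 0.053 before, so that lists were compared with another background. The words were sought among all 4096 sequences of 6 bases in the 3′ UTRs of 11395 tested genes. Each gene was represented by its annotated transcript with the longest 3′ UTR, whether or not these cells express it. A gene said to carry a word may thus have transcripts without it. The measure was the rank z of carriers against other genes after correction for 3′ UTR length and GC content, with 1000 permutations. In simulated data the word step ranked the shifted word first for 5 of 5 words at each of the shifts -0.1 and -0.2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.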

Results

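The series asks which genes depend on PHF20L1, a nuclear protein with Tudor domains and a PHD finger that binds methylated lysines. Transcript levels were compared between 3 siControl and 3 siPHF20L1 libraries of MDA-MB-231 breast cancer cells, each of about 17200000 to 17500000 fragments as estimated from the steps of the low values. Values are FPKM as deposited, given as mean ± SD (n = 3 libraries per group), and log2 differences are on the log2(FPKM + 1) scale.

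PHF20L1 itself (Entrez 51105) fell from 13.7 ± 1.82 FPKM (SD, n = 3) in siControl to 2.57 ± 0.231 FPKM (SD, n = 3) in siPHF20L1 libraries. The siControl libraries lay at 15.75, 12.48 and 12.73 FPKM and the siPHF20L1 libraries at 2.67, 2.31 and 2.74 FPKM, so that every library followed its label. The log2 difference was -2.03 (SE 0.10, limma, adjusted p = 1.46e-06). It was -2.19 between the libraries numbered 1 and -1.95 between those numbered 2 and 3. PHF20 (Entrez 51230), the paralog and a member of the NSL histone acetyltransferase complex, was at 15.9 ± 0.359 FPKM in siControl and 14.6 ± 0.410 FPKM in siPHF20L1 libraries. Its log2 difference of -0.12 did not pass the threshold (limma, adjusted p = 0.116). It did with the replicate number as a block (limma, adjusted p = 0.0230), with quantile normalization (0.0255), with median-ratio size factors (0.0253) and in the libraries numbered 2 and 3 alone (0.0381), and over the 15 alternatives of scaling, filter, block and libraries the adjusted p of the gene PHF20 lay between 0.0230 and 0.393.

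**Figure D1:**
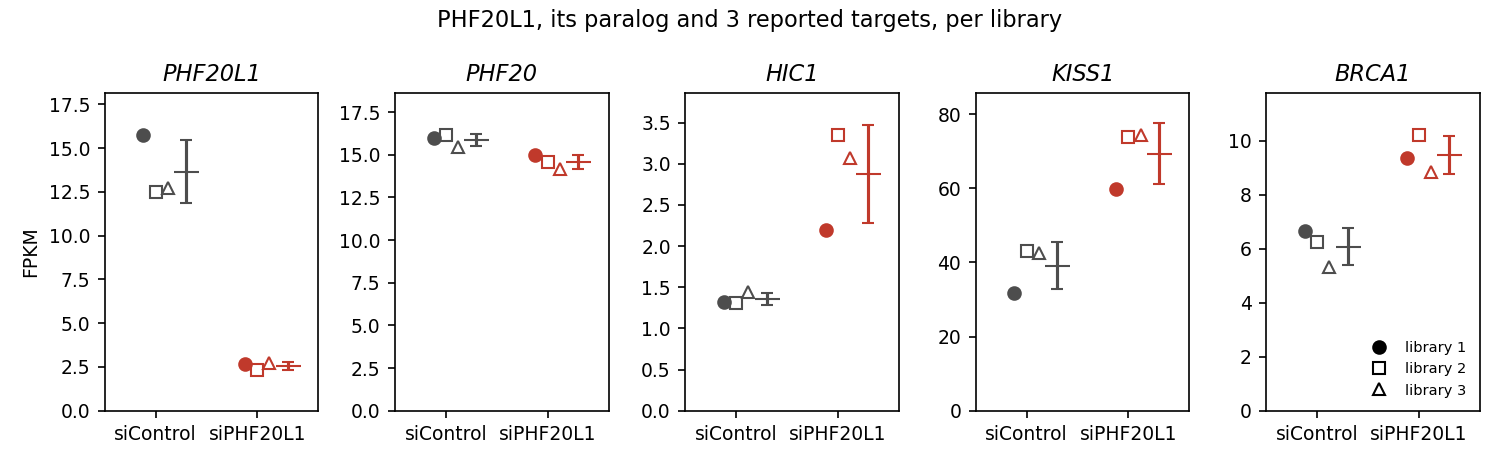
FPKM of PHF20L1, PHF20, HIC1, KISS1 and BRCA1 in each library (y axes start at 0; symbols mark the libraries numbered 1, 2 and 3, and the bars show mean ± SD, n = 3 per group). PHF20L1 lies between 12.48 and 15.75 FPKM in siControl and between 2.31 and 2.74 FPKM in siPHF20L1 libraries, and HIC1, KISS1 and BRCA1 are higher in every siPHF20L1 library than in any siControl library.

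The 3 genes that the study reported as targets of PHF20L1 were all higher after the knockdown. KISS1 (Entrez 3814), which encodes a peptide precursor known as a metastasis suppressor, rose from 39.1 ± 6.34 to 69.3 ± 8.24 FPKM (log2 difference 0.82, SE 0.13, limma, adjusted p = 0.000685). HIC1 (Entrez 3090), a transcriptional repressor, rose from 1.36 ± 0.072 to 2.87 ± 0.6 FPKM (log2 difference 0.71, SE 0.12, limma, adjusted p = 0.000902). BRCA1 (Entrez 672), which acts in homologous recombination, rose from 6.06 ± 0.685 to 9.46 ± 0.693 FPKM (log2 difference 0.57, SE 0.09, limma, adjusted p = 0.000784). All 3 also passed when adjusted over the list alone, which is not independent evidence, since the study named them on this cell line and may have chosen them on these libraries. The log2 differences of KISS1, HIC1 and BRCA1 were 0.89, 0.46 and 0.44 between the libraries numbered 1, and 0.78, 0.83 and 0.64 between those numbered 2 and 3.

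Across all genes, 3926 were higher and 2851 lower in siPHF20L1 libraries, 6777 of the 11560 tested (limma, adjusted p under 0.05). Most of these differences were small. At least 2-fold on the log2 scale, 386 genes were higher and 218 lower, and 91.1% of the 6777 genes stayed under that size. With a pseudocount of 0.1 in place of 1, 685 genes were higher and 312 lower by at least 2-fold. The groups did not overlap in 63.7% of the genes tested, against 10% by chance for 3 against 3 libraries. The first principal component held 85.4% of the variance and separated the groups. The second held 10.2% and set the libraries numbered 1 of both groups apart from the others. With the libraries numbered 2 and 3 alone, 4651 genes were higher and 3585 lower. The excess of higher genes depended on the scaling. Quantile normalization gave 3354 higher and 3495 lower, median-ratio size factors 3446 and 3390, and scaling to equal sums 3983 and 2618.

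**Figure D2:**
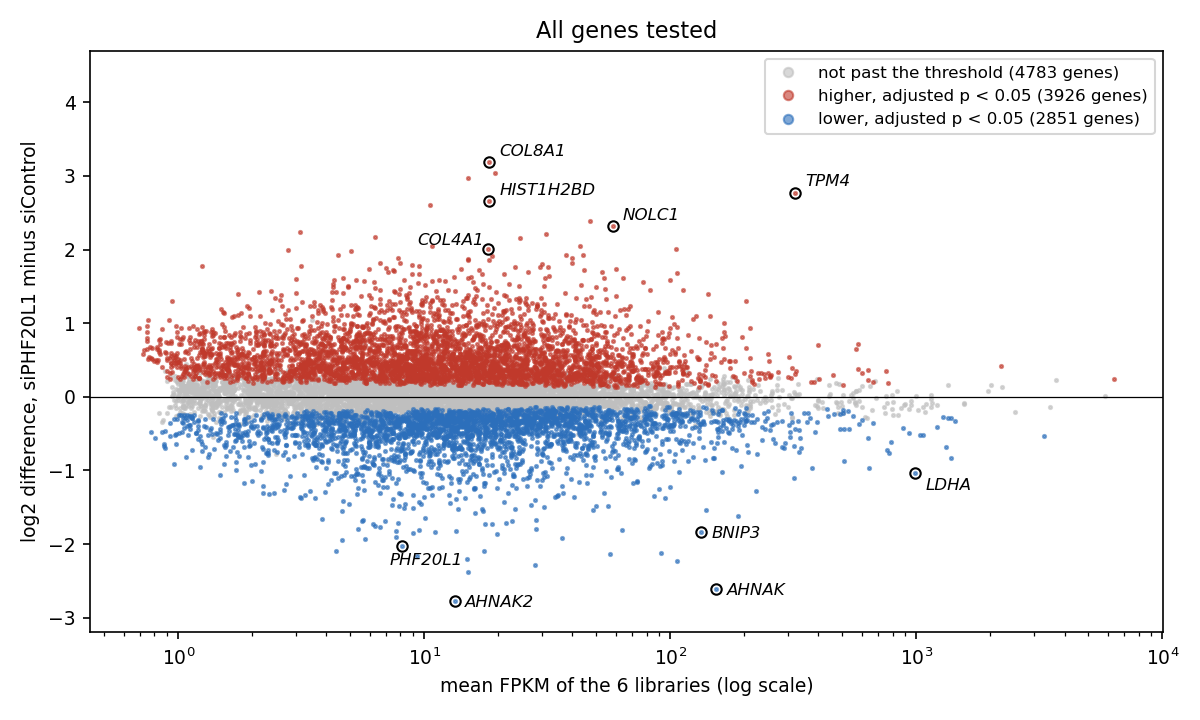
Log2 difference (siPHF20L1 minus siControl, y axis) of each of the 11560 genes tested against its mean FPKM over the 6 libraries (x axis, log scale), with 3926 genes higher in red, 2851 lower in blue and the others in grey. Circles mark named genes, among them COL8A1 at 3.19, TPM4 at 2.77, PHF20L1 at -2.03 and AHNAK2 at -2.77.

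On the log2(FPKM + 1) scale, which understates low genes, the largest rises were those of COL8A1, a short-chain collagen (Entrez 1295; 2.81 ± 0.165 to 33.7 ± 1.08 FPKM), IGFBPL1 (3.39 ± 0.130 to 35.2 ± 0.928 FPKM) and CD22, a lectin known from B cells (2.63 ± 0.184 to 27.4 ± 0.370 FPKM). TPM4, an actin-binding tropomyosin, rose from 80.7 ± 5.23 to 559 ± 63.1 FPKM. The histone gene HIST1H2BD rose 7.52-fold, the actin-bundling LCP1 8.31-fold, the glucosamine-6-phosphate deaminase GNPDA1 5.53-fold and the nucleolar protein gene NOLC1 5.19-fold. CCDC190, FOXP4, IFT27 and NFKBIB completed the 12 largest rises, with log2 differences of 2.23, 2.21, 2.17 and 2.16. By the ratio of mean FPKM, CCDC190 came first of the 12, with 12.9-fold (0.447 ± 0.202 to 5.78 ± 0.816 FPKM). Over these 12 genes the highest adjusted p of limma was 2.73e-06.

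AHNAK2 and AHNAK, which encode giant scaffold proteins, fell most on the log2(FPKM + 1) scale, from 23.9 ± 1.27 to 2.65 ± 0.096 FPKM and from 265 ± 38.8 to 42.3 ± 3.17 FPKM. The kinase genes NEK7 (25.8 ± 2.73 to 4.13 ± 0.181 FPKM) and MAP2K1, which encodes MEK1 (47.6 ± 0.710 to 8.96 ± 0.318 FPKM), followed. The other large falls were those of ERH (log2 difference -2.24), PCYOX1 (-2.20), SPAG1 (-2.16), DAZAP2 (-2.13), the glyoxalase gene GLO1 (-2.12), the sterol desaturase gene SC5D (-2.09) and MPV17L2 (-2.09). By the ratio of mean FPKM, the fall of SC5D (7.41-fold) was larger than that of AHNAK (6.27-fold). PHF20L1 itself was the last of the 12, whose highest adjusted p of limma was 1.46e-06. The longest annotated 3′ UTRs of 11 of these 12 genes, AHNAK being the exception, hold the words CAAGAT or TAAGGA. These are carried by 1637 of the 2840 lower genes with a 3′ UTR of any length. Among the 11395 genes with one of at least 50 nt, they are carried by 75.7% of those lower by at least 2-fold and by 48.6% of all others. Neither share is corrected for 3′ UTR length or GC content. Among the 12 largest rises, 2 hold these words, CCDC190 and LCP1. The words were picked on the log2 differences of these same genes, so these shares are not independent evidence. Picked on 1 random part of the genes, CAAGAT had a z of -6.99 in the other 5698, and picked on those it had -7.63 in the rest. Each of the genes named here that passed the threshold kept its direction between the libraries numbered 1 and between those numbered 2 and 3.

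Genes of sugar metabolism were lower as a group. Of the 23 glycolysis genes tested, 16 fell, 3 rose and 4 did not pass (17 lower and 3 higher adjusted over the list alone). LDHA, which makes lactate from pyruvate, fell from 1331 ± 88.0 to 649 ± 79.3 FPKM, TPI1 from 659 ± 18.7 to 358 ± 9.35 FPKM and PGK1 from 193 ± 4.49 to 109 ± 2.15 FPKM, while the glucose transporter gene SLC2A3 rose from 13.9 ± 0.419 to 31.7 ± 1.92 FPKM. The median log2 difference was -0.41 (camera of limma, adjusted p = 0.000474), and -0.40 and -0.43 within the libraries numbered 1 and those numbered 2 and 3. With an estimated correlation the adjusted p was 0.66 (camera), and over the 15 alternatives it lay between 8.44e-05 and 0.0086. Of the 23 genes, 9 carry CAAGAT or TAAGGA in their 3′ UTR. With all carriers left out, in the list and among the other genes, the list passed (camera, adjusted p = 0.0297).

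Of 25 genes listed for the tricarboxylic acid cycle and pyruvate dehydrogenase, 12 fell, 4 rose and 9 did not pass, with the same counts adjusted over the list alone. The list also holds the cytosolic ACO1, IDH1 and MDH1 and the carboxylase gene PC, which lie outside the mitochondrial cycle itself. The cytosolic isocitrate dehydrogenase gene IDH1 fell from 33.6 ± 1.98 to 9.49 ± 0.342 FPKM, the pyruvate dehydrogenase genes DLAT and PDHB fell 2.49-fold and 2.27-fold, and the succinate dehydrogenase gene SDHD fell 1.77-fold. The median was -0.18 (camera, adjusted p = 0.0169), and -0.11 and -0.22 within the numbers. The adjusted p of camera was 0.612 with an estimated correlation and between 0.0043 and 0.0378 over the 15 alternatives. With all genes that carry CAAGAT or TAAGGA in their 3′ UTR left out, 14 of the 25 among them, the median was -0.09 and the list did not pass (camera, adjusted p = 0.372). Of 30 nuclear genes of oxidative phosphorylation, 12 were lower (11 adjusted over the list alone) and 3 higher, with ATP5B down from 358 ± 14.6 to 257 ± 10.2 FPKM, and the list did not pass (camera, adjusted p = 0.0762). It did in the libraries numbered 2 and 3 alone (camera, adjusted p = 0.0362), without the filter on low values (0.0297), without siControl replicate 1 (0.0275) and without siPHF20L1 replicate 2 (0.0439), within a range of 0.0275 to 0.267 over the 15 alternatives.

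In the hypoxia response list, 13 of 24 genes fell, 5 rose and 6 did not pass, with the same counts adjusted over the list alone. The mitophagy gene BNIP3 fell from 208 ± 9.76 to 57.7 ± 2.56 FPKM, the carbonic anhydrase gene CA9 from 2.94 ± 0.391 to 0.75 ± 0.053 FPKM, INSIG2 from 7.60 ± 0.4 to 3.15 ± 0.299 FPKM, and the oxygen sensor gene EGLN1 from 16.4 ± 0.394 to 10.1 ± 0.324 FPKM. The median was -0.27 (camera, adjusted p = 0.0408), and -0.18 and -0.27 within the numbers. This call was lost with the replicate block (camera, adjusted p = 0.0551), in the libraries numbered 2 and 3 alone (0.0629), without siPHF20L1 replicate 1 (0.0617) and with an estimated correlation (adjusted p = 0.612), and the range over the 15 alternatives was 0.0189 to 0.0629. The words CAAGAT or TAAGGA are carried by 14 of the 24 genes, and with all carriers left out, in the list and elsewhere, the adjusted p of camera was 0.0495.

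Mitotic genes were lower on balance, with 19 of 32 lower, 6 higher and 7 not past the threshold (20 and 6 adjusted over the list alone). ECT2, a regulator of cytokinesis, fell from 49.3 ± 4.34 to 18.7 ± 1.74 FPKM and the phosphatase gene CDC25C from 18.1 ± 0.727 to 7.53 ± 0.042 FPKM. In the other direction, BIRC5, which encodes survivin, rose from 19.9 ± 1.81 to 49.1 ± 3.69 FPKM and the centromeric histone gene CENPA from 13.7 ± 0.581 to 23.5 ± 0.741 FPKM. The median was -0.26 (camera, adjusted p = 0.0146), and -0.24 and -0.26 within the numbers. The adjusted p of camera was 0.66 with an estimated correlation and 0.00196 to 0.0378 over the 15 alternatives. It was 0.0366 with all carriers of CAAGAT or TAAGGA left out, 13 members among them. Genes of DNA replication and the G1/S transition went both ways, with 13 of 33 higher and 7 lower (camera, adjusted p = 0.949). E2F1 rose from 19.7 ± 1.45 to 32.4 ± 3.77 FPKM, and the cyclin gene CCNE2 fell from 12.6 ± 1.04 to 2.82 ± 0.236 FPKM.

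Genes of the ATF4 and amino acid response, which is switched on by amino acid shortage and stress of the endoplasmic reticulum, were higher. Of 21 genes, 13 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone. ATF4 rose from 116 ± 6.08 to 215 ± 5.40 FPKM, TRIB3 from 5.93 ± 0.644 to 20.5 ± 3.20 FPKM and NUPR1 from 2.95 ± 0.464 to 12.9 ± 0.589 FPKM, while VLDLR fell from 9.37 ± 0.363 to 3.95 ± 0.275 FPKM. The median was 0.39 (camera, adjusted p = 0.0169), and 0.37 and 0.42 within the numbers. The adjusted p of camera was 0.612 with an estimated correlation and 0.0043 to 0.0266 over the 15 alternatives. It was 0.0297 with all carriers of CAAGAT or TAAGGA left out, 9 members among them.

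Histone genes of the replication-dependent kind, whose transcripts mostly lack a poly-A tail and are thus read only in part in these poly-A libraries, were also higher. Of 13 genes, 10 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone. HIST1H2BD rose from 4.31 ± 0.426 to 32.4 ± 1.75 FPKM, HIST1H2AC from 7.35 ± 0.166 to 29.2 ± 2.36 FPKM, HIST1H2BK from 92.0 ± 4.65 to 198 ± 7.58 FPKM and HIST1H2BJ from 3.62 ± 0.413 to 12.9 ± 1.25 FPKM. The median was 1.10 (camera, adjusted p = 0.0169), and 1.16 and 1.04 within the numbers. The adjusted p of camera was 0.66 with an estimated correlation and 0.0091 to 0.0404 over the 15 alternatives. With all carriers of CAAGAT or TAAGGA left out, 2 members among them, the median was 0.96 and the list did not pass (camera, adjusted p = 0.115). The genes it was compared with changed too, since the median over all genes was then 0.091 against 0.053. None of the 6 list calls held with an estimated correlation, where 3 lists had an unadjusted p of camera under 0.05. The loss does not by itself show that members vary together, since that setting also has far fewer degrees of freedom. For the tricarboxylic acid cycle list the estimated correlation was 0.01, the preset value. Its adjusted p still went from 0.0169 to 0.612 (camera). Values of single histone genes are uncertain, since near-identical copies can share reads.

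**Figure D3:**
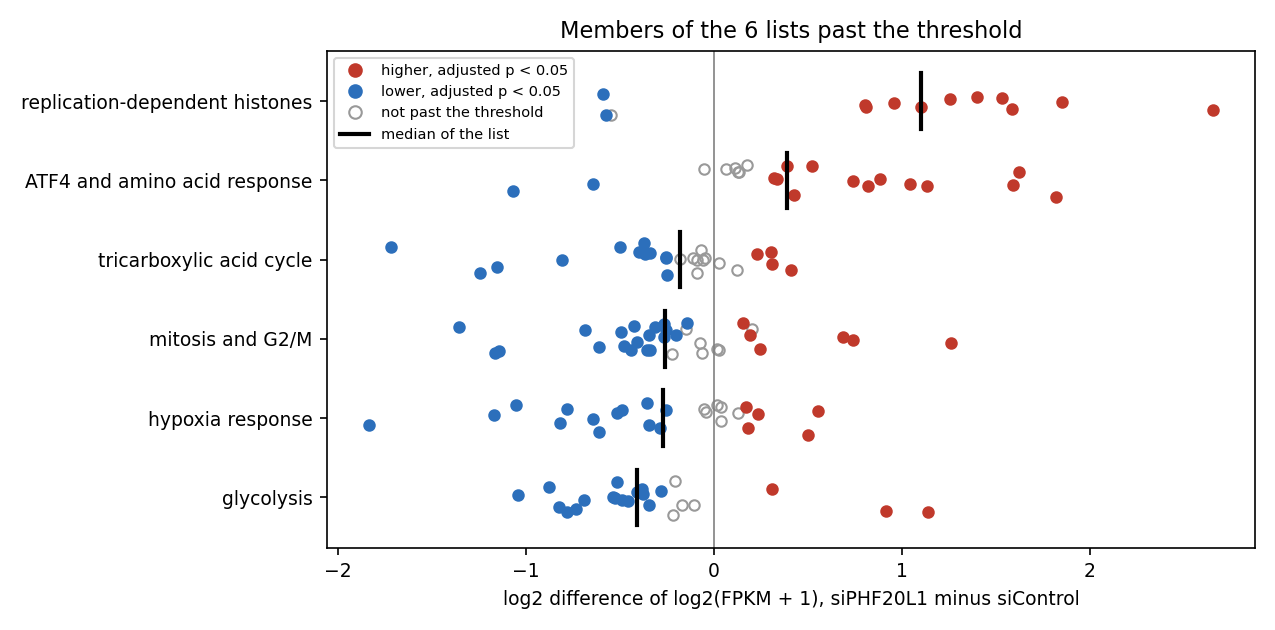
Log2 difference (x axis, siPHF20L1 minus siControl, log2(FPKM + 1)) of every tested member of the 6 lists past the threshold, 1 point per gene, filled where limma's adjusted p is under 0.05, with the median of each list as a bar. The medians are 1.10 for histones and 0.39 for the ATF4 list, and -0.18, -0.26, -0.27 and -0.41 for the tricarboxylic acid cycle, mitosis, hypoxia and glycolysis lists.

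The remaining 35 lists tested did not pass with camera, and most had members in both directions. The counts were the same when adjusted over the list alone unless given. In the lists of the NuRD complex, p53 targets, metastasis suppressors, homologous recombination, epithelial junctions, adhesion, YAP and TEAD targets, luminal epithelium, fatty acids, NRF2, apoptosis, cytokines, and MYC and ribosome biogenesis, the median, the mean and the direction of camera did not share 1 sign.

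Among chromatin regulators, the Polycomb list had 5 of 24 genes higher (6 adjusted over the list alone) and 9 lower (camera, adjusted p = 0.5), with JARID2 up from 6.51 ± 0.291 to 15.5 ± 0.520 FPKM and PHC1 down from 7.43 ± 0.170 to 4.02 ± 0.284 FPKM. The NuRD deacetylase complex had 4 of 15 higher and 4 lower (camera, adjusted p = 0.946). GATAD2A rose from 24.7 ± 0.721 to 54.5 ± 1.37 FPKM and MTA2 fell from 99.9 ± 3.94 to 59.5 ± 1.94 FPKM. In the list of PHF20 and the NSL complex, 2 of 9 were higher (1 adjusted over the list alone), HCFC1 among them, and the other 7 did not pass (camera, adjusted p = 0.946). With the replicate number as a block 4 were higher and 3 lower (limma). KAT8 and WDR5 were among the higher ones with the block (limma, adjusted p = 0.00120 and 0.00444), against an adjusted p of 0.0968 and 0.108 without it. Over the 15 alternatives the adjusted p of the gene KAT8 reached 0.254 and that of the gene WDR5 0.406. Of 12 genes of the DNA methylation machinery, 3 were higher and 7 lower (camera, adjusted p = 0.189, and 0.042 without the filter on low values, within a range of 0.042 to 0.285 over the 15 alternatives). The methyltransferase gene SETD7 rose from 3.58 ± 0.268 to 17.9 ± 1.29 FPKM, and the dioxygenase gene TET2 fell from 5.27 ± 0.648 to 2.38 ± 0.209 FPKM.

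Of 24 growth inhibitors and tumour suppressors, 11 were higher, HIC1 and BRCA1 among them, and 7 lower, or 8 adjusted over the list alone (camera, adjusted p = 0.850). TXNIP rose from 56.0 ± 2.04 to 105 ± 3.68 FPKM, and CDKN1A, which encodes the cell cycle inhibitor p21, fell from 50.1 ± 0.640 to 19.2 ± 0.978 FPKM. The p53 targets split evenly, with 8 of 24 higher and 8 lower (camera, adjusted p = 0.946), and GDF15 rose from 2.21 ± 0.528 to 9.74 ± 1.71 FPKM. Homologous recombination genes had 6 of 27 higher, BRCA1, RAD51D and PALB2 among them, and 6 lower (camera, adjusted p = 0.814), and with the block 10 were higher and 12 lower. The metastasis suppressors had 4 of 13 higher, KISS1 among them, and 3 lower (camera, adjusted p = 0.946). CD82, a tetraspanin of this list, fell from 99.6 ± 4.57 to 27.8 ± 1.23 FPKM.

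Genes of invasion and shape moved in both directions. In the mesenchymal list 4 of 12 were higher and 7 lower (camera, adjusted p = 0.413). The lysyl oxidase gene LOXL2 fell from 209 ± 9.26 to 71.6 ± 2.72 FPKM, AXL from 499 ± 9.23 to 255 ± 5.25 FPKM and vimentin (VIM) from 1624 ± 17.4 to 1015 ± 7.89 FPKM, while SNAI2 rose from 2.17 ± 0.211 to 6.27 ± 0.536 FPKM. Epithelial junction genes had 4 of 13 higher and 3 lower (camera, adjusted p = 0.946), and with the block 6 higher and 5 lower. Extracellular matrix and protease genes had 10 of 22 higher (11 adjusted over the list alone) and 6 lower (camera, adjusted p = 0.814), with COL4A1 up from 6.66 ± 0.309 to 29.8 ± 0.410 FPKM. Adhesion and migration genes had 8 of 28 higher and 8 lower (camera, adjusted p = 0.644), and the GTPase gene RAC1 rose from 78.0 ± 1.40 to 208 ± 1.27 FPKM. The YAP and TEAD targets had 5 of 19 higher (7 adjusted over the list alone) and 8 lower (camera, adjusted p = 0.780), and the TGF-beta targets 5 of 17 higher and 8 lower (camera, adjusted p = 0.213).

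Among immune genes, 16 of 31 interferon-stimulated genes were higher (17 adjusted over the list alone) and 5 lower (camera, adjusted p = 0.215). IFI44 rose from 13.4 ± 1.34 to 31.8 ± 2.49 FPKM and HERC5 from 10.2 ± 0.816 to 18.7 ± 0.983 FPKM, and IFITM1 fell from 6.76 ± 0.526 to 2.84 ± 0.555 FPKM. Antigen presentation genes had 7 of 17 higher and 2 lower (camera, adjusted p = 0.559), and with the block 10 higher and 4 lower. In the list of inflammatory cytokines and NF-kB, 5 of 19 were higher and 6 lower (camera, adjusted p = 0.814), its median was 0.08 and its mean -0.18. The cytokine genes IL11 and IL1B fell from 31.5 ± 2.68 to 7.96 ± 1.01 FPKM and from 15.3 ± 0.195 to 3.68 ± 0.388 FPKM.

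Markers of other cell types did not pass as groups. Luminal breast epithelium had 3 of 11 genes higher and 4 lower, or 5 adjusted over the list alone (camera, adjusted p = 0.850), keratinocytes 1 of 5 higher and 1 lower (camera, adjusted p = 0.814), and blood cells 1 of 5 higher, LCP1, and the other 4 not past the threshold (camera, adjusted p = 0.814). With the block 2 keratinocyte markers were higher and 3 lower, and 1 blood cell marker was higher and 1 lower. Of 5 fibroblast markers tested, 3 were higher and 1 lower (camera, adjusted p = 0.517), with the contractile genes TAGLN up from 13 ± 1.22 to 46.3 ± 2.55 FPKM and ACTA2 up from 0.970 ± 0.131 to 3.99 ± 0.361 FPKM. Of 3 endothelial markers tested, too few for the list test, ROBO4 was higher. Of the lower genes named beside the lists, the largest falls aside, those that carry CAAGAT or TAAGGA in the 3′ UTR are TPI1, PGK1, IDH1, DLAT, PDHB, SDHD, BNIP3, INSIG2, EGLN1, ECT2, CDC25C, CCNE2, VLDLR, MTA2, TET2, CD82, LOXL2, AXL, VIM and IL11, and those that do not are LDHA, CA9, CDKN1A, PHC1, IFITM1, IL1B and ATP5B. Higher genes carry these words too, the largest rises aside, namely HIC1, BRCA1, NUPR1, HIST1H2AC, HIST1H2BJ, JARID2, GATAD2A, SETD7, TXNIP, RAD51D and ROBO4. The higher genes KISS1, SLC2A3, BIRC5, CENPA, E2F1, ATF4, TRIB3, HIST1H2BK, HCFC1, GDF15, PALB2, SNAI2, COL4A1, RAC1, IFI44, HERC5, TAGLN and ACTA2 do not.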

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

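The scalings to equal sums and by median ratios, the libraries numbered 2 and 3 alone or averaged, the lists without the 3′ UTR words, and the lists with quantile normalization, a pseudocount of 0.1 or no filter were chosen after the data were seen. PHF20L1 was lower under all 15 alternatives, by log2 differences from -2.36 to -1.93 (limma, adjusted p from 2.45e-09 to 7.8e-05). Of the 180 other genes the naming rule allows, 168 kept their side of the threshold under the same 15. No gene past the threshold changed direction, and some genes not past it changed sign, KDR, ESAM and CSF1R with quantile normalization and LYZ without siControl replicate 1. The count of 6777 genes became 8792 with the replicate block, 6849 with quantile normalization, 4887 with the libraries 2 and 3 averaged and 5735 to 6940 with 1 library left out, all within 1.5 times. Of those 8792 genes, 6777 were the main calls in the same direction. The share of calls that were higher, 57.9%, lay between 49% and 60.3% under every scaling. A pseudocount of 0.1 raised the genes at least 2-fold higher from 386 to 685, because it shrinks low values less. The 6 lists past the threshold became 12 without the filter, which adds genes near 0 to the comparison (gained were DNA methylation, oxidative phosphorylation, unfolded protein response, ribosomal protein, autophagy and RNA interference), 0 with an estimated correlation, where the lowest adjusted p was 0.612 (camera; 3 lists at an unadjusted p under 0.05), and 30 with fry, which tests whether genes of a list move on balance one way and does not compare them with other genes. With fry the direction of the NuRD (median 0.054), p53 target (0.028), MYC and ribosome biogenesis (0.079) and apoptosis (0.036) lists was up, where camera gave down relative to the other genes. With 1 library left out, 5 to 8 lists passed. The hypoxia list was also lost with quantile normalization (camera, adjusted p = 0.0601) and the stricter filter (0.0529), within a range of 0.0189 to 0.0629. The cause was not tested. Without the carriers of CAAGAT or TAAGGA, the tricarboxylic acid cycle list was lost with a median of -0.091 against -0.182 (camera, adjusted p = 0.372), and the histone list with a median of 0.961 against 1.10 (camera, adjusted p = 0.115), both with fewer members and genes tested, and the oxidative phosphorylation (0.0297), immediate early (0.0297) and autophagy (0.0366) lists passed. The block brought 7 of these genes past the threshold (PHF20, KAT8, WDR5, HOXD3, KRT17, ITGB4 and CD68), ended the call of the hypoxia list, and changed no other call among the 180 genes and 41 lists. The planned tests and scaling for counts were not run because the values are FPKM, and scaling by library size alone is the deposited FPKM. Depth limits low genes most, since 1 fragment in 1 kb is worth 0.0573 to 0.0583 FPKM at the estimated depth.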

Other observations

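The tests of 3′ UTR length and GC content, of the word in PHF20L1 transcripts, of a swap of libraries and of the other splits of the samples were chosen after their results were seen, as were the words themselves and the test of GO terms. In the unfolded protein response list 11 of 20 were higher and 1 lower (camera, adjusted p = 0.0790), with the chaperone gene HSPA5 up from 127 ± 5.37 to 202 ± 3.51 FPKM and MANF up from 63.3 ± 2.59 to 115 ± 0.140 FPKM. Of 22 autophagy and lysosome genes, 12 were higher (13 adjusted over the list alone) and 2 lower (3 adjusted over the list alone), with the cathepsin gene CTSB at 28.6 ± 2.56 and 13.4 ± 0.673 FPKM (camera, adjusted p = 0.105). Neither list passed, and with an estimated correlation the adjusted p of camera was 0.618 and 0.66. Quantile normalization (camera, adjusted p = 0.0378 and 0.0418) and leaving out the filter brought both past the threshold, within ranges of 0.031 to 0.117 and 0.0418 to 0.15 over the 15 alternatives. In lipid synthesis, 7 of 23 cholesterol genes were higher and 10 lower, or 11 adjusted over the list alone (camera, adjusted p = 0.413), with SC5D down. Of 17 fatty acid genes, 6 were higher and 7 lower (camera, adjusted p = 0.814), and FASN fell from 84.8 ± 6.73 to 41.0 ± 5.02 FPKM and ACLY from 115 ± 3.86 to 61.4 ± 1.26 FPKM. Heat shock genes had 5 of 14 higher and 2 lower (camera, adjusted p = 0.814), the NRF2 list 5 of 18 higher and 7 lower (camera, adjusted p = 0.559), and the apoptosis list 6 of 22 higher and 7 lower (camera, adjusted p = 0.946).

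Among genes of RNA handling, 2 of 13 of the RNA interference machinery were higher and 8 lower (camera, adjusted p = 0.0822, and 0.0381 without the filter on low values, within a range of 0.0381 to 0.139 over the 15 alternatives). DICER1 fell from 21.6 ± 3.62 to 5.39 ± 0.719 FPKM and DROSHA rose from 12.6 ± 0.908 to 25.8 ± 1.78 FPKM. Ribosomal protein genes had 1 of 30 higher, RPL11, and 7 lower (camera, adjusted p = 0.0726), with an adjusted p of 0.0127 in the libraries numbered 2 and 3 alone, 0.0297 without the filter on low values, 0.00706 without siControl replicate 1, 0.0217 without siPHF20L1 replicate 2 and a range of 0.00706 to 0.994 over the 15 alternatives. With the replicate block 4 of its genes were higher and 14 lower. The median of this list was 0.029 with quantile normalization and -0.101 as deposited. In the list of MYC and ribosome biogenesis 9 of 20 were higher, NOLC1 among them, and 7 lower, with nucleolin (NCL) down from 217 ± 4.93 to 107 ± 12 FPKM (camera, adjusted p = 0.946). Of 18 immediate early genes, 5 were higher and 8 lower (camera, adjusted p = 0.417), and of 5 HOX genes tested, HOXB3 and HOXB9 were higher (camera, adjusted p = 0.417). Of the lower genes named up to here, CTSB, ACLY, NCL, DICER1 and SC5D carry CAAGAT or TAAGGA in the 3′ UTR and FASN does not. Of the higher ones, HSPA5 and HOXB3 do, and MANF, DROSHA, RPL11, HOXB9 and NOLC1 do not. Of 935 GO terms of 10 to 300 tested genes as annotated in the deposited tables, 1 passed. It was viral gene expression, a term made up largely of ribosomal protein genes, with 20 of 73 lower and 1 higher (camera, adjusted p = 0.0393, and adjusted p = 0.955 with an estimated correlation).

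The real grouping gave 6777 genes (limma), or 7312 at an unadjusted p under 0.05. The highest of the other 9 splits gave 0, and at an unadjusted p under 0.05 they gave 5 to 314 genes. Each of these splits has siControl and siPHF20L1 libraries on both sides, so the difference between the groups widens their spread. Their low counts follow from this and do not measure false calls. The splits that part all 3 same-numbered pairs, as the real one does, gave 0 as well, and the others keep a pair together. The 6 libraries allow only 10 splits, of which 1 gave as many genes, and 10 are too few for a share under 0.05.

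Genes lower in siPHF20L1 libraries carried the word CAAGAT in their 3′ UTR more often than others. Of the 2822 lower genes with a 3′ UTR of at least 50 nt, 42.9% held it, against 35.7% expected from 3′ UTRs of like length and GC content. Of the 218 lower by at least 2-fold, 61.9% did, against 38.9% expected. A trend with length and GC content is argued against by the z of -10.32 left after correction, beyond the 5.01 of the most extreme of 1000 permutations (p = 0.001, the smallest they can give), and a difference of the libraries numbered 1 by a z of -10.25 in those numbered 2 and 3 alone. A candidate explanation is seed pairing of the siRNA with other transcripts. Genes with the word in the 3′ UTR alone were lower than genes with it in the coding sequence alone by a small margin (-0.030, 95% bootstrap interval -0.055 to -0.002). The latter (mean -0.009) already lay below genes with the word in neither (0.071). These means were corrected for length and GC content of the 3′ UTR, not of the coding sequence. CAAGAT was also picked for its 3′ UTR shift in these genes, which favours that side, so this margin cannot decide for seed pairing. Genes with 2 or more sites were lower than genes with 1 (-0.043, interval -0.079 to -0.007). All 8 coding PHF20L1 transcripts hold the word, as they do 13.9% of all words, 7 times in the longest of 6237 nt. Only PHF20L1-209 and PHF20L1-210 hold it in the 3′ UTR. The siRNA sequence and a second siRNA were not used here, so for any single gene an effect of PHF20L1 loss and one of such pairing stay open, IDH1, MAP2K1 and DICER1 among those that carry CAAGAT or TAAGGA, the latter word with a z of only -4.49 (permutation p = 0.025), inside the permuted 5.01.

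Genes higher in siPHF20L1 libraries carried GGAGAA, and the related CGGAGA, more often. Other words with the core GGAGA did so too, with a corrected z of 8.31 for TGGAGA, 7.92 for AGGAGA, 6.64 for GGAGAG and 5.56 for GGAGAT. The words thus share the core. Their z also grows with the number of carriers, 1046 for CGGAGA against 5190 for TGGAGA and 5372 for AGGAGA. Like z values therefore do not mean shifts of like size. The z of GGAGAA was 9.01 after correction for 3′ UTR length and GC content and 9.02 in the libraries numbered 2 and 3 alone, both beyond the permuted 5.01, which argues against a trend with length and GC content and against the libraries numbered 1. Carriers of CGGAGA had a mean log2 difference of 0.262 (1046 genes), against 0.052 in the others, both without correction for 3′ UTR length and GC content. The same means were 0.116 and 0.033 for TGGAGA and 0.115 and 0.031 for AGGAGA, also uncorrected. The gap was thus widest for CGGAGA among these words. The correction moved the z of CGGAGA from 11.84 to 8.57. A release from seed pairing of the control siRNA may contribute, since genes with 2 or more GGAGAA sites were higher than genes with 1 (0.045, interval 0.018 to 0.073). However, genes with the site in the 3′ UTR alone and in the coding sequence alone could not be told apart (0.006, interval -0.021 to 0.036). Both lay above genes with it in neither (means -0.010, -0.015 and -0.085). These means, too, were not corrected for length or GC content of the coding sequence. An untransfected sample, which would show the effect of the control siRNA, was not analysed here, and loss of PHF20L1 stays open as an untested alternative.

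The libraries numbered 1 of both groups deviated together from those numbered 2 and 3. A swap of these libraries between the groups is argued against by PHF20L1, which in the siPHF20L1 library numbered 1 lay below the lowest siControl library by a log2 difference of -1.88. The deviations followed transcript GC content, with r = -0.69 in siControl and -0.68 in siPHF20L1 across 11499 genes, which are not independent replicates, and less closely transcript length (r = 0.42 and 0.31). These values are consistent with a difference in library preparation or sequencing shared by the libraries numbered 1, and no biological explanation was tested. The difference between the groups itself had r = 0.12 with GC content and -0.01 with length.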
